A study of Mus musculus with 10 samples.

How the data were processed

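RNA was sequenced from whole cochleas of mice at postnatal day 8, in 5 libraries labelled Pknox2-/- and 5 labelled Pknox2+/+. The labels describe cochleas kept in RNAlater, total RNA and Illumina libraries made by standard protocols. They give the group of each library in its title and genotype. The series text speaks of independent biological samples, so p-values of single genes measure the spread between those samples, but it does not say whether a library holds 1 pup or several.

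The deposited file is a table of raw read counts per gene, with 27179 Entrez gene IDs and a column for each of the 10 libraries. HISAT2, featureCounts and limma, and the mouse genome build mm10, are named without versions or roles, per the submitters' processing notes. The gene annotation, the strand setting of the counting, any filter and any pooling are not given in the sources used here. Without a strand setting, reads from overlapping genes on opposite strands cannot be told apart. The values were whole numbers whose totals differed between libraries. Totals ran from 16.6 M to 19.4 M counts per library. No column was left unmapped to a library.

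Gene symbols and positions came from a RefSeq table of GRCm38, the assembly that mm10 also names, which matched 25275 of the IDs. A further 18 IDs were named through GENCODE release M21, and 1886 had no symbol. IDs without a symbol took 0.473% to 1.24% of a library's counts. They stayed in the tests and are not named. Transcript length and GC content were taken from the longest GENCODE transcript of each gene, with coding transcripts preferred, and were known for 93.6% of the tested genes.

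The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with all 10 libraries and the group as the only term. Libraries were scaled by TMM. Genes with low counts were removed by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16018 genes. P-values were adjusted by the Benjamini-Hochberg method over those genes, and a gene was called at an adjusted p under 0.05. Log2 fold changes are knockout minus wild type, so a positive value is higher in the libraries labelled knockout. Standard errors were computed as the size of the log2 fold change divided by the square root of F. Levels are CPM (counts scaled to the library total) after TMM scaling, as mean ± SD over 5 libraries.

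The fit was tested on simulated counts drawn for each gene on its own from the real means, dispersions and library sizes. Of 16018 genes 200 were changed, all above 1 CPM. In the simulation it called 17.9% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 97.0% of those changed 4-fold. Of its calls, 5.30% were unchanged genes. The simulation held no differences between libraries that many genes share, which the real data hold, so these shares need not carry over to the real comparison.

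Before the data were examined, 40 gene lists were fixed for cell types of the cochlea, for tissue that can come along in the dissection and for pathways. The 39 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera compares the genes of a list with all other genes. With the preset correlation its p-values rest mainly on the spread between genes and do not measure the spread between samples. P-values were adjusted over the 39 lists. The list of mitochondrially encoded genes had no tested member. For members, the number called over all tested genes and the number called when adjusted over the list alone were both counted. A gene can stand on several lists.

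The genes to be named were also fixed by a rule. It takes Pknox2, then up to 10 called genes in each direction by smallest p. Where fewer than 5 pass in a direction, the 5 with the smallest unadjusted p are named as not having passed, and models known only by a clone or Gm name are passed over. From each list it takes up to 4 called members, or the values of up to 2 members with the smallest p where none was called. Tested members of the TALE homeobox family are summarised. A gene outside the rule is named as such.

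Alternatives were relative log expression and upper-quartile scaling, no filter on low counts and a stricter one (CPM above 1 in at least 5 libraries), DESeq2 1.42.0, limma-voom with and without sample quality weights, the replicate number as a block, 1 surrogate variable (sva 3.50.0), Y-linked expression as a covariate, a threshold of 0.1, a test against a fold change of 1.2, and the removal of each library in turn. For lists, camera was also run with an estimated correlation, and fry, which tests whether a list's genes move one way on balance. Chosen only after the data were seen were a fit with the first principal component as a covariate, a fit without the libraries labelled knockout 2, 3 and 5, and a fit with each library's trend over transcript length and GC content removed. Libraries of a group were compared by chi-square before averaging, and the smallest value per degree of freedom was 10.1, so that no pair differed by as little as sampling noise. The share of genes with an unadjusted p under 0.05 within 10 Mb of Pknox2 was compared with other genes by Fisher's exact test, two-sided. Figures were drawn with matplotlib 3.10.9.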

Results

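Whole cochleas of 8-day-old mice were profiled by RNA sequencing in 5 libraries labelled Pknox2 knockout and 5 wild-type libraries. Library totals lay between 16.6 and 19.4 M counts. The series title names PKNOX2 as a transcription factor of the mammalian cochlea, and the only comparison the design holds asks which cochlear transcripts differ when both copies of the gene are labelled as lost.

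Pknox2 (Entrez 208076, chromosome 9, 36890979 to 37147342, GRCm38) encodes a homeodomain protein of the TALE family and is reported first because its level could show whether the labels hold. Its level was 19.9 ± 1.96 CPM in wild type and 21.1 ± 4.38 CPM in the libraries labelled knockout (SD, n = 5 each). The log2 fold change was 0.08 (SE 0.146, adjusted p = 0.736, edgeR quasi-likelihood test). None of the 5 libraries labelled knockout lay below the lowest wild-type library. The count covers the whole gene, and the extent of the deleted part is not given in the sources used here. A transcript that lacks only part of its sequence would still be counted, so this value does not check the labels, and every direction below rests on them.

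Ceacam16 and Thbs4 fell and Tectb rose in the libraries labelled knockout, and these were the 3 genes called among 16018 tested. Ceacam16 and Tectb both encode proteins of the tectorial membrane, the acellular gel over the hair cells. Ceacam16 (Entrez 330483, chromosome 7, 19852097 to 19871426, GRCm38) went from 19.6 ± 2.71 CPM in wild type to 4.45 ± 0.665 CPM (SD, n = 5 each). Tectb, which encodes beta-tectorin (Entrez 21684, chromosome 19, 55180726 to 55196313), went from 128 ± 31.1 to 384 ± 103 CPM. Thbs4 (Entrez 21828, chromosome 13, 92751586 to 92794818), which encodes the matrix glycoprotein thrombospondin 4, went from 7.84 ± 1.21 to 3.16 ± 0.411 CPM.

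For each of the 3 genes, all 5 libraries labelled knockout lay outside the range of the 5 wild-type libraries. By edgeR's quasi-likelihood test the log2 fold change was -2.14 for Ceacam16 (SE 0.151, adjusted p = 0.000102), 1.58 for Tectb (SE 0.207, adjusted p = 0.0300) and -1.31 for Thbs4 (SE 0.165, adjusted p = 0.0300). The gene model Gm19345, which is counted separately and was looked at only because it overlaps Ceacam16, had a log2 fold change of -1.06 (SE 0.315, adjusted p = 0.214) at 2.39 ± 0.646 CPM in wild type, and the strand setting of the counting is unknown. With Y-linked expression as a covariate none of the 3 was called, while the log2 fold changes were -1.99 for Ceacam16 (SE 0.248), 1.44 for Tectb (SE 0.314) and -1.10 for Thbs4 (SE 0.269). When single libraries were left out, Ceacam16 was called in every fit, Tectb only without knockout 1 and Thbs4 only without knockout 1 or wild type 2.

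**Figure D1:**
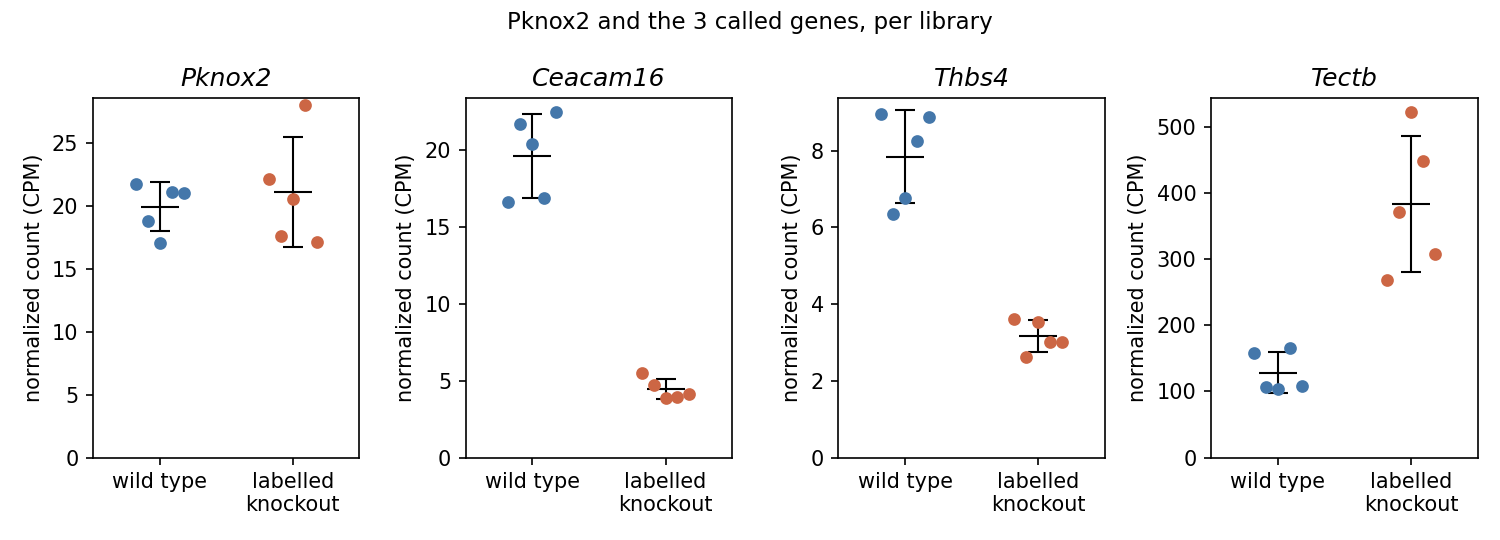
Normalized counts (CPM, linear axes from 0) of Pknox2 and the 3 called genes in each library, with points for single libraries and black bars for the mean ± SD (n = 5 per group). Pknox2 overlaps between the groups, at means of 19.9 and 21.1 CPM, while Ceacam16, Thbs4 and Tectb do not overlap.

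A further 4 genes lay between an adjusted p of 0.05 and 0.1 in the same test. Ncmap, a protein of non-compact myelin, had a log2 fold change of -0.66 (SE 0.0960, adjusted p = 0.0610), and Coch, which encodes cochlin of the otic matrix, had -0.74 (SE 0.117, adjusted p = 0.0812). Pik3cd had -0.59 and Tnfrsf4 had 1.60. Of the genes with the next smallest p above 0, Galnt6 had 0.58, Glb1, the lysosomal beta-galactosidase, had 0.73 and Podnl1 had 0.79. An unadjusted p under 0.05 was reached by 3215 genes, where 801 would be expected with no change. That number was 662 of 16463 without knockout 2, 3 and 5, 1529 with the first component as a covariate, 293 with Y-linked expression as a covariate and 1737 to 5692 when single libraries were left out. Differences between libraries that many genes share can move this number widely, so the excess is not a count of changed genes.

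The number of called genes depended on the tool and on single libraries. DESeq2 called 331 genes, limma-voom with quality weights called 6259, and edgeR called 166 without knockout 1, 2 without wild type 2 and 1 without any other single library. With knockout 2, 3 and 5 left out together edgeR called 1 gene, Ceacam16.

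Single libraries differed within the groups as well as between them. The libraries labelled knockout 2, 3 and 5 scored 73.5, 41.2 and 45.1 on the first principal component, which held 56.6% of the variance, and the other 7 scored from -42.3 to 2.77. Ribosomal protein genes took 6.73%, 5.38% and 5.23% of the counts in those 3 libraries and 2.57% to 4.40% in the others. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 209 CPM in knockout 1 and to between 0 and 11.3 CPM in the other 4 knockout libraries. In wild type they summed to between 197 and 225 CPM in 4 libraries and to 102 CPM in wild type 5. Xist, the transcript of the inactive X chromosome, was at 498 to 684 CPM in knockout 2 to 5, at 392 CPM in wild type 5 and at 27.8 CPM in wild type 2, and at 0.119 to 0.679 CPM in the other 4 libraries. The sex makeup of the libraries therefore differed between the groups.

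**Figure D2:**
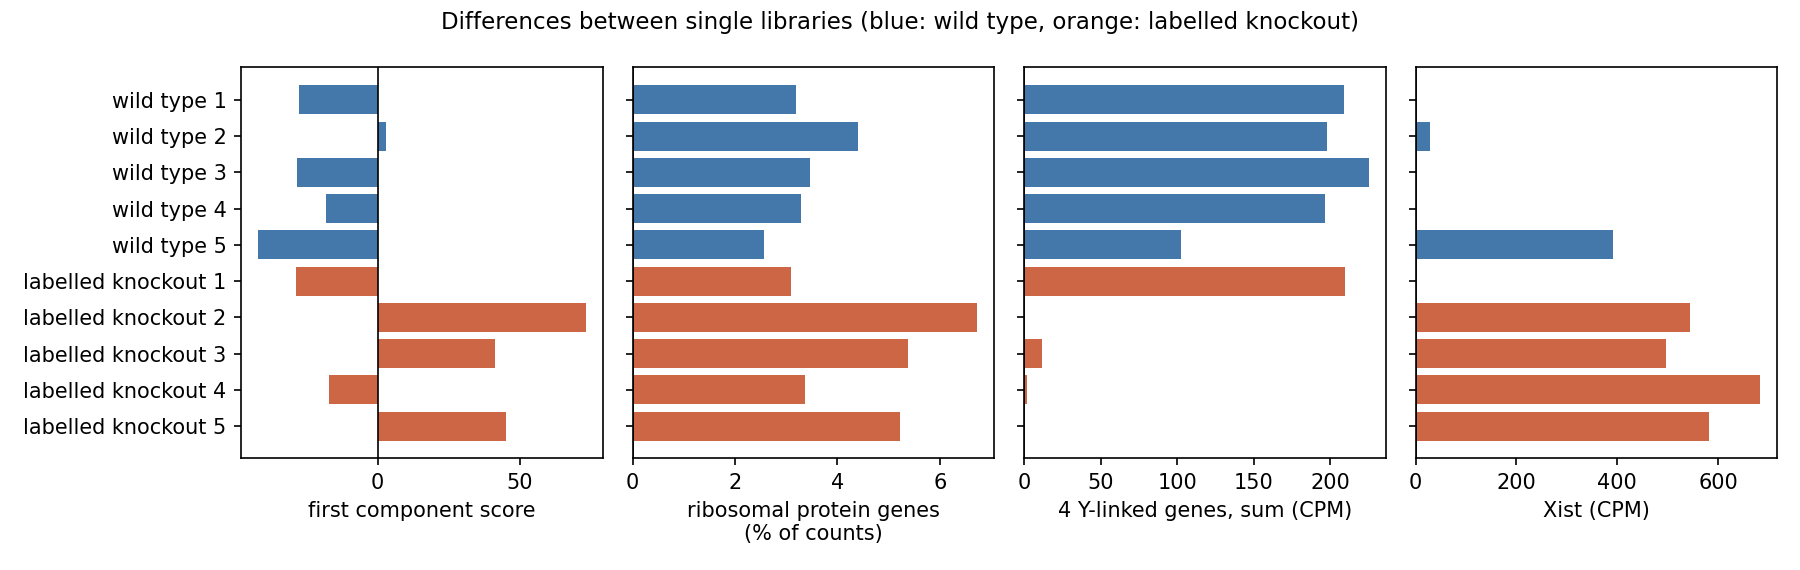
First component score, share of counts in ribosomal protein genes (%), summed Y-linked genes (CPM) and Xist (CPM), with a bar for each of the 10 libraries. Knockout 2, 3 and 5 have the 3 highest component scores and ribosomal shares, and knockout 2 to 5 and wild type 5 have Xist at 392 CPM or more.

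Of the 39 gene lists tested, 12 passed with camera's preset correlation, 6 higher and 6 lower in the libraries labelled knockout. With an estimated correlation none passed (adjusted p = 0.806 or more), and fry passed none (adjusted p = 0.122 or more).

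Genes of Schwann cells and myelin fell as a list in the libraries labelled knockout, with a median log2 fold change of -0.49 and 29 of 30 members below 0 (adjusted p = 1.82e-10 with camera, and adjusted p = 0.806 with an estimated correlation). No member was called over all genes, while 16 passed below 0 and 1 above 0 adjusted over the list alone. The peripheral myelin protein gene Pmp22 went from 2244 ± 203 to 1515 ± 185 CPM (SD, n = 5 each), with a log2 fold change of -0.57. The median was -0.17 without knockout 2, 3 and 5. Spiral ganglion neuron genes fell as a list, with a median of -0.39 and 40 of 49 members below 0 (adjusted p = 1.53e-05, and adjusted p = 0.806 with an estimated correlation). None was called over all genes or adjusted over the list alone. The synaptic gene Snap25 had -0.79. Without knockout 2, 3 and 5 the neuron list had a median of -0.08 and an adjusted p = 0.783, and with the first component as a covariate -0.16 and an adjusted p = 0.424.

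Genes of cochlear potassium homeostasis and of strial basal and spindle cells were lower as lists, while the other strial lists did not pass. The list for cochlear potassium and ion homeostasis had a median of -0.21 (adjusted p = 0.0184, and adjusted p = 0.806 with an estimated correlation), with 20 of 27 members below 0. Adjusted over the list alone 3 members passed, namely Kcnj16 (log2 fold change -0.72), the sodium pump subunit gene Atp1b1 (-0.62) and Slc26a4 (-0.45), which encodes the anion exchanger pendrin. Strial basal and spindle cell genes had a median of -0.38 (adjusted p = 0.0299, and adjusted p = 0.806 with an estimated correlation), with 11 of 13 below 0 and Slc26a4 passing adjusted over the list alone. Neither list passed without knockout 2, 3 and 5, at medians of -0.04 (adjusted p = 0.453) and -0.08 (adjusted p = 0.551), or with the first component as a covariate, at -0.015 (adjusted p = 0.481) and -0.07 (adjusted p = 0.567). With Y-linked expression as a covariate the potassium list turned to 0.025 (adjusted p = 0.437) and the basal cell list had -0.023 (adjusted p = 0.392). The surrogate variable ended both calls too, at -0.06 (adjusted p = 0.0793) and -0.17 (adjusted p = 0.0919), and removing the length and GC trend ended the basal cell call at -0.12 (adjusted p = 0.0729). Leaving out wild type 4 ended both calls (adjusted p = 0.0663 for potassium and adjusted p = 0.117 for basal cells), and leaving out knockout 4 ended the first (adjusted p = 0.0538). Strial marginal cell genes (median -0.16, adjusted p = 0.294; Abcg1 -0.24, Slc12a2 -0.44) and intermediate cell and melanocyte genes (-0.09, adjusted p = 0.531; Kit -0.37, Kcnj10 -0.33) did not pass.

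Genes of bone rose as lists. Osteoclast genes had a median of 0.31 with 13 of 15 members above 0 (adjusted p = 7.06e-06, and adjusted p = 0.806 with an estimated correlation), and 8 passed adjusted over the list alone. They included Dcstamp, needed for osteoclast fusion, which went from 16.0 ± 3.55 to 33.3 ± 8.62 CPM, and Mmp9, from 710.0 ± 131 to 1164 ± 180 CPM (SD, n = 5 each). Osteoblast and bone matrix genes had a median of 0.19 with 20 of 22 above 0 (adjusted p = 0.000436, and adjusted p = 0.806 with an estimated correlation), and 4 passed adjusted over the list alone, among them Ifitm5 (0.96) and Pth1r (0.84). Macrophage and microglia genes had a median of 0.30 (adjusted p = 0.0284, and adjusted p = 0.806 with an estimated correlation), with 3 passing adjusted over the list alone, among them Tmem119 (0.49) and Cd68 (0.77). Without knockout 2, 3 and 5 the macrophage list had a median of -0.03 (adjusted p = 0.717), while the osteoclast list had 0.36 and the osteoblast list 0.27. The macrophage median was 0.18 without knockout 2. Leaving out wild type 4 or wild type 5 ended the macrophage call, at adjusted p = 0.0939 and adjusted p = 0.0925. It ended as well with the surrogate variable (0.0024, adjusted p = 0.384), Y-linked expression (0.06, adjusted p = 0.229), the first component (-0.06, adjusted p = 0.869) and the length and GC trend removed (0.09, adjusted p = 0.233).

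Genes of blood cells fell as lists in 2 of 3 cases, but they also differed inside wild type. Per library, the median log2 deviation of erythroid genes from their means over all libraries was -0.83 in wild type 4. It was -0.09 to 0.88 in the other wild types and -0.70 to 0.24 in the knockout libraries. Lymphocyte genes had 0.52 to 0.90 in wild type 1 to 3 and -0.33 and -0.43 in wild type 4 and 5. The knockout libraries had -0.84 to 0.13. Neutrophil genes had 0.57 to 1.09, -0.71 and -0.79, and -1.20 to 0.35 there. Erythroid genes had a median of -0.47 with 24 of 25 members below 0 (adjusted p = 0.00771, and adjusted p = 0.839 with an estimated correlation), with Tfrc at -0.43 and none passing adjusted over the list alone. Lymphocyte genes had a median of -0.43 with 17 of 21 below 0 (adjusted p = 0.0131, and adjusted p = 0.839 with an estimated correlation). Adjusted over the list alone 3 passed, among them the recombinase gene Rag1 (-1.51) and the B-cell factor gene Pax5 (-1.82). Neutrophil genes had a median of -0.35 and did not pass (adjusted p = 0.267), although Mmp9 passed above 0 adjusted over the list alone and Ear2 had -2.47. The neutrophil list did pass without knockout 2, 3 and 5 (-1.06, adjusted p = 3.18e-08), with the first component (-1.03, adjusted p = 1.37e-08), the surrogate variable (-0.83, adjusted p = 9.25e-07) or Y-linked expression (-0.66, adjusted p = 0.0298) as a covariate, and with the length and GC trend removed (-0.60, adjusted p = 0.000476). It also passed when knockout 2 (-0.49, adjusted p = 0.0410), wild type 4 (-0.53, adjusted p = 0.00619) or wild type 5 (-0.53, adjusted p = 0.00295) was left out. The lymphocyte list had -0.91 (adjusted p = 3.04e-08) without knockout 2, 3 and 5, a fit that keeps only knockout 1 and knockout 4. Y-linked expression as a covariate ended the erythroid call (median -0.22, adjusted p = 0.116). Leaving out wild type 2 ended that call (median -0.33, adjusted p = 0.153) and the lymphocyte call (-0.24, adjusted p = 0.129). Leaving out knockout 4 ended them too, at adjusted p = 0.207 and adjusted p = 0.189, and so did leaving out wild type 3 for the erythroid list (adjusted p = 0.0602) and knockout 1 for the lymphocyte list (adjusted p = 0.0771).

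Ribosomal protein genes rose as a list, with all 82 members above 0 and a median of 0.53 (adjusted p = 2.01e-15, and adjusted p = 0.806 with an estimated correlation). Rpl10a had 0.72 and Rps20 had 0.80, and no member passed adjusted over the list alone. Many of these genes have near-identical pseudogenes, so their counts are uncertain. Without knockout 2, 3 and 5 the median was -0.06 (adjusted p = 0.418), with the first component as a covariate it was -0.07 (adjusted p = 0.0134), and with Y-linked expression as a covariate it was 0.0022 (adjusted p = 0.609). Heat shock and unfolded protein response genes had a median of 0.17 (adjusted p = 0.00771, and adjusted p = 0.806 with an estimated correlation), with Pdia6 at 0.51 and Hspa5 at 0.52 and none passing adjusted over the list alone. The list had 0.07 (adjusted p = 0.0685) without knockout 2, 3 and 5, 0.06 (adjusted p = 0.0780) with the surrogate variable, 0.035 (adjusted p = 0.481) with the first component as a covariate and 0.09 (adjusted p = 0.292) with the length and GC trend removed.

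Vestibular and otoconial genes rose as a list, with a median of 0.28 and 15 of 18 members above 0 (adjusted p = 0.0284, and adjusted p = 0.806 with an estimated correlation). Tectb was called over all genes, and adjusted over the list alone 3 members passed above 0, among them the matrix gene Tnc (0.65), and 1 below 0. Without knockout 2, 3 and 5 the median was 0.13. Leaving out knockout 1, knockout 3 or wild type 2 ended the call, at adjusted p = 0.103, adjusted p = 0.0927 and adjusted p = 0.0591, and so did removing the length and GC trend (0.24, adjusted p = 0.108).

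The lists for the sensory epithelium did not pass, although the tectorial membrane and supporting cell lists hold called genes. Tectorial membrane genes had a median of 0.03, a mean of -0.10 and a test direction below 0 (adjusted p = 0.735). Ceacam16 and Tectb were called over all genes, in opposite directions, and 2 members rose and 3 fell adjusted over the list alone, Coch among the latter. Supporting cell genes had a median of -0.16 with a mean of 0.05 (adjusted p = 0.770). Tectb was called over all genes, and 4 members rose adjusted over the list alone, Tectb and Matn4 among them. Hair cell identity genes had a median of 0.10 (adjusted p = 0.704; Barhl1 1.2, Tbx2 0.25), outer hair cell genes -0.21 (adjusted p = 0.277; Bcl11b 0.76), stereocilia genes -0.08 (adjusted p = 0.704; Espnl 0.61, Clrn1 -0.57) and hair cell synapse genes -0.14 (adjusted p = 0.0829, and adjusted p = 0.0340 without wild type 3; Stx1a 0.51). Hearing loss genes had a median of -0.09 with 76 of 115 below 0 (adjusted p = 0.0590, and adjusted p = 0.0130 to 0.0478 in 7 other fits), and 2 rose and 2 fell adjusted over the list alone. The 16 tested TALE homeobox genes, the family of Pknox2 itself, had a median of 0.13 with 12 above 0 (adjusted p = 0.0590), with the smallest p for Irx6 (0.77) and Tgif2 (0.27).

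The remaining lists did not pass either. Their medians were -0.10 for otic fibrocytes (adjusted p = 0.406; Emilin2 -0.47), -0.11 for central nervous system cells (adjusted p = 0.895; Cspg4 0.36, Cbln1 1.01 and 0.62 without knockout 2), -0.19 for choroid plexus (adjusted p = 0.528; Kl -0.89, Ttr 1.57 and 0.67 without knockout 2) and -0.15 for endothelial cells and pericytes (adjusted p = 0.528; Egfl7 0.64). Cartilage had -0.04 with a mean of 0.11 (adjusted p = 0.704; Matn1 0.78, Mia 0.65), skeletal muscle 0.04 with a test direction below 0 (adjusted p = 0.979; Tnni1 1.02, Myl1 0.59), middle ear epithelium 0.07 (adjusted p = 0.979; Lypd2 0.95, Foxj1 -0.26) and adipocytes 0.11 (adjusted p = 0.483; Plin4 -0.49 and -0.27 without wild type 3, Cebpa 0.24). Immediate early genes had 0.07 (adjusted p = 0.0805; Ier2 0.78, Junb 0.42), hypoxia and glycolysis 0.08 (adjusted p = 0.704; Ndrg1 -0.37, P4ha1 0.26), the cell cycle -0.22 (adjusted p = 0.267; Ccne2 -0.62, Cenpe -0.46) and cholesterol synthesis -0.10 (adjusted p = 0.242; Hmgcs1 -0.36). Extracellular matrix genes had 0.08 (adjusted p = 0.406; Col1a1 0.52), Notch signalling 0.08 (adjusted p = 0.459; Id1 0.64, Hes1 0.64), Wnt signalling -0.02 (adjusted p = 0.770; Dkk1 0.55, Wnt2b -0.83) and thyroid hormone and retinoid signalling 0.02 (adjusted p = 0.369; Slco1c1 -0.46, Crym 0.90). No member of these lists was called over all genes. Adjusted over the list alone, Coch passed below 0 among fibrocyte genes and Lypd2 above 0 among middle ear genes. Of endothelial and pericyte genes 2 passed above 0 (Cspg4 and Egfl7) and 1 below 0, and 6 immediate early genes passed above 0, Ier2 and Junb among them. Tnc and Col1a1 passed above 0 among matrix genes, and 2 thyroid hormone and retinoid genes passed above 0 and 1 below 0.

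**Figure D3:**
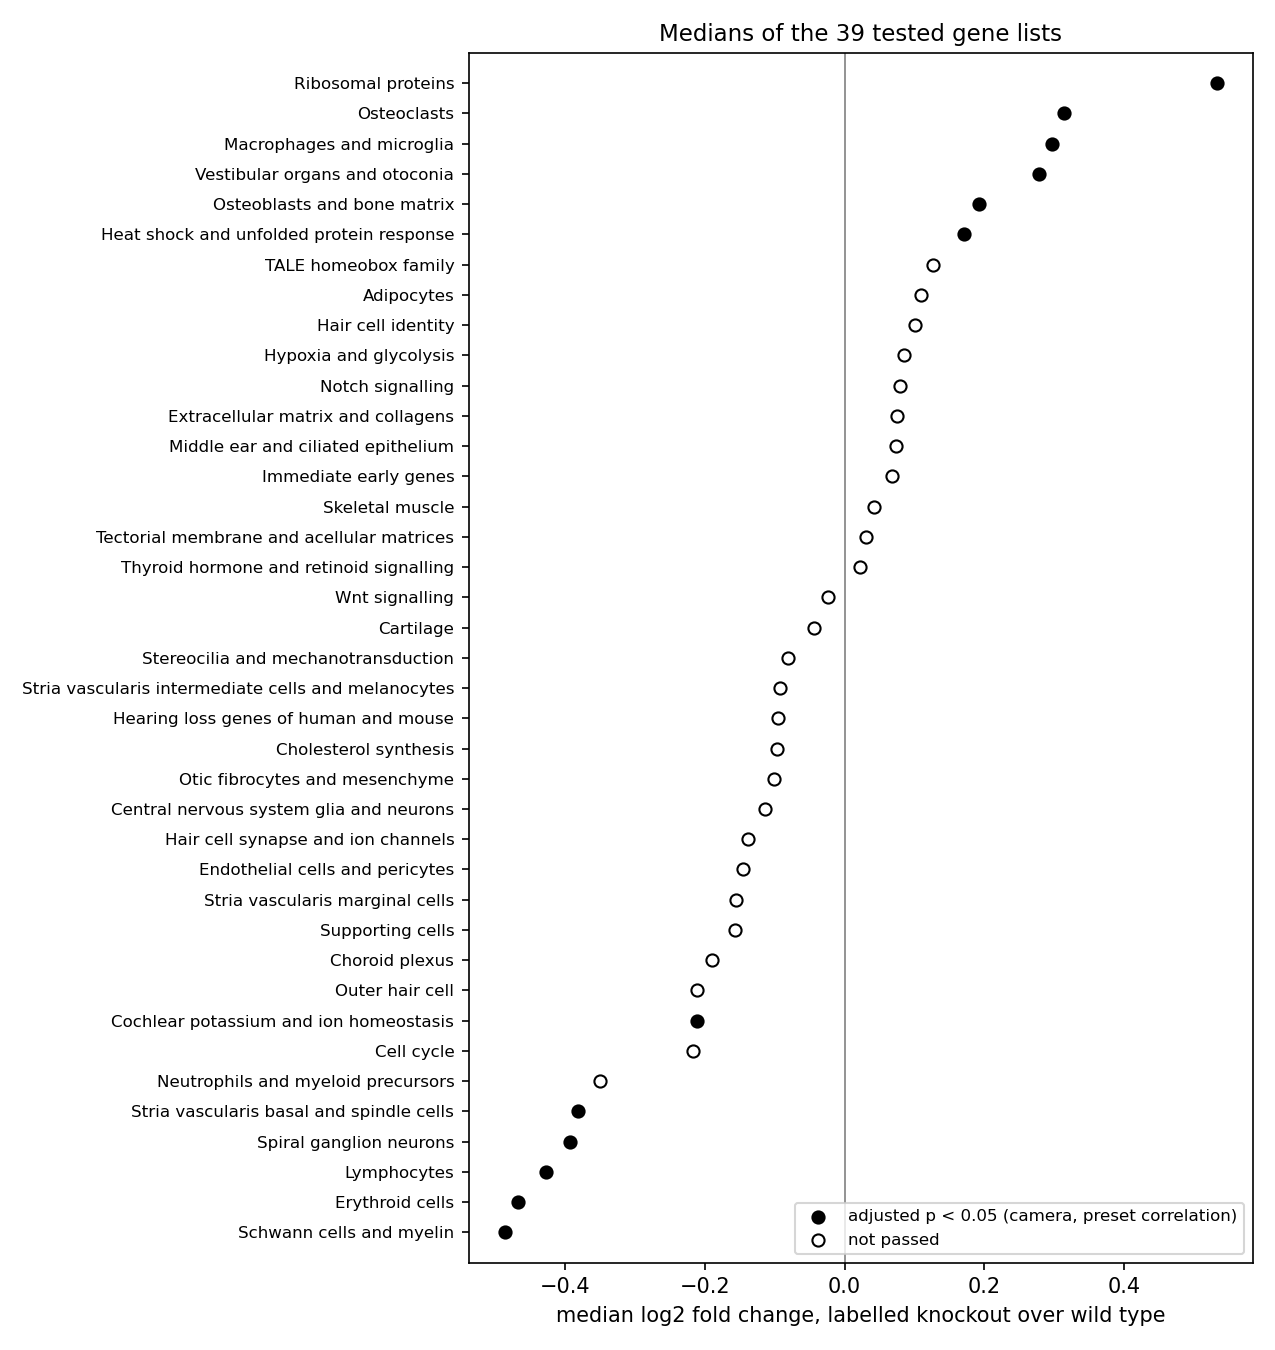
Median log2 fold change, labelled knockout over wild type, for each of the 39 tested gene lists, with filled points for the 12 that passed camera at an adjusted p under 0.05 and open points for the others. The medians run from -0.49 for Schwann cells and myelin to 0.53 for ribosomal proteins.

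Among 128 tested genes within 10 Mb of Pknox2, 0 were called by edgeR, and only 3 were called over all genes. An unadjusted p under 0.05 was reached by 21.1% of them and by 20.1% of the other genes (two-sided Fisher's exact test, p = 0.740).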

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

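Chosen only after the results were seen were the tests of vestibular tissue, of sex for Ceacam16 alone, of sex behind the first component, of the length trend as the whole cause and of the loadings of other cell types, the counts of splits for DESeq2 and for lists, and the use of a 95% interval in the tests with covariates.

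Values far from the rest of their group stood out for the sex-linked transcripts. Knockout 1 had the highest Y-linked sum of its group, 209 CPM where the next had 11.3 CPM, and the lowest Xist, 0.679 CPM where the next had 498 CPM. Wild type 5 had the lowest Y-linked sum of its group, 102 CPM where the next had 197 CPM, and the highest Xist, 392 CPM where the next had 27.8 CPM. Both kinds of transcript were high in wild type 5.

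Among named genes, Ttr, a choroid plexus transcript, was at 82.6 CPM in knockout 2, where the next knockout library had 24.3 CPM, and Cbln1, a cerebellar transcript, was at 19.3 CPM there, where the next had 8.59 CPM. Wild type 5 had the lowest wild-type Cbln1, at 3.39 CPM. Ncmap was lowest in knockout 3 at 53.8 CPM within its group, and Dkk1 was lowest in knockout 1 at 50.2 CPM. Wild type 2 was the lowest of its group for Kcnj10 at 144 CPM and for Cspg4 at 30.9 CPM, and the highest for Egfl7 at 80.4 CPM. Wild type 4 was the highest of its group for Espnl at 8.54 CPM and for Pmp22 at 2594 CPM, and wild type 3 for Plin4 at 10.3 CPM. Wild type 3 also had the highest total of its group, 19.4 M counts. In all, 16 of 242 groups of 5 values had such a library, or 6.61%, where chance gives about 5%, and 4 of the 16 are the sex-linked values.

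The first pattern weighed is the 3 called genes, Ceacam16, Thbs4 and Tectb. Of 100 of the 126 splits of the libraries into 5 and 5, the real one included, 3 gave as many called genes. This is fewer than 5 in 100, the limit set beforehand for chance. The other 2 of these splits kept knockout 2, 3 and 5 on the same side, as the real one does, and the highest called 4480 genes. Most splits part those 3 libraries, so the count does not exclude chance among splits that keep them together. That structure among the samples is described next. Against a library-wide trend, each gene kept at least 87.8% of its log2 fold change with the first component as a covariate, with 95% intervals beyond 50% of it, but the condition set beforehand, that all 3 stay called, was not met, since Tectb (1.58, SE 0.207, of which 95.1% was kept, SE 0.233, adjusted p = 0.0894) and Thbs4 (-1.31, SE 0.165, to -1.15, SE 0.196, adjusted p = 0.0991) lost their calls as the SE grew and the changes shrank. On vestibular tissue as the source of Tectb, the other 17 vestibular genes had a median of 0.26 (95% bootstrap interval 0.037 to 0.44). This lies below 0.79, which is 50% of the Tectb change and the limit set for the test. Some of these genes also stand on lists of other tissues, which can hold the median down. The interval covers the spread between genes and not between samples, so vestibular tissue is not excluded. Sex makeup is argued against for Ceacam16, though largely by 1 library. Its log2 fold change went from -2.14 (SE 0.151) to -1.99 (SE 0.248) with Y-linked expression as a covariate, with the 95% bound nearest 0 at -1.45. For Tectb (1.58, SE 0.207, to 1.44, SE 0.314) and Thbs4 (-1.31, SE 0.165, to -1.10, SE 0.269) sex and genotype cannot be told apart. The smallest share kept was 84.3%, with intervals that reach below 50%. The covariate was the log2 of the summed Y-linked CPM plus 1. On that scale wild type 5 lies closer to the other wild types than to knockout 2 to 5. In that fit mostly knockout 1 therefore breaks the link between sex and group. The genotype in the labels stays open as the biological explanation.

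The second pattern is the distance of knockout 2, 3 and 5 from the other 7 libraries on the first component, whose loadings followed transcript length (Spearman -0.68 across genes, which are not independent replicates). A length-dependent difference between libraries may be part of it. With the fitted trend over length and GC removed, the lowest of the 3 still scored 35.7 above the highest of the others, against 38.4 before. The gaps come from different components, with 46.6% of the variance after the removal and 56.6% before. The trend as fitted is therefore not the whole of it, while a length effect that the fit missed stays open. Counting knockout libraries alone could not decide on sex, because all 3 libraries have low Y-linked expression. Only 1 further knockout library with low Y-linked expression, knockout 4, lay among the wild types on the component without X- and Y-linked genes. That count left out wild type 5, with Xist at 392 CPM and Y-linked genes at 102 CPM. On that component knockout 4 (Xist 684 CPM) scored -18.6 and wild type 5 scored -41.9. Knockout 2, 3 and 5 scored 40.2 to 70.9 there. High Xist thus occurred at both ends. However, wild type 5 held both kinds of transcript, and knockout 4 is a single library, so these values cannot decide. Sex stays open as a cause. Fewer neurons and Schwann cells went with the test set beforehand, since regressing out their median ended the separation, but so did 18 of 37 other lists, so that test decides little. Such a loss would raise all other cell types alike. The loadings of 16 lists of other cell types differed (Kruskal-Wallis statistic with a permutation test over 10000 shuffles of genes, which are not independent, p = 1.00e-04). After Bonferroni correction 8 of 120 pairs were apart, such as neutrophils at a median of 0.79 SD and strial marginal cells at -0.50 SD. Lists can also load differently through any other variation among the libraries, such as the length trend, so this test cannot decide. Its criterion was changed 2 times after values were seen. The criterion before found 1 of 16 lists with its whole 95% bootstrap interval below 0, no more than chance gives (one-sided exact binomial p = 0.333). Fewer neurons and Schwann cells and an effect of genotype therefore stay open.

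Counts by other routes were less specific to the groups. As many as the 331 genes called by DESeq2 were found in 5 of the 100 splits, the real one included, so chance is not excluded there, and the highest other split had 5553. As many as 12 lists were called in 54 of the 100 splits, with 22 in the highest other, so chance is not excluded for the number of lists. The 2 splits with the most genes called by edgeR both kept knockout 2, 3 and 5 on the same side.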

How the results depend on the processing

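Chosen only after the data were seen were the fits with the first component as a covariate, without knockout 2, 3 and 5, and with the trend over transcript length and GC content removed. Ceacam16 kept its direction in all 24 fits that gave it a value and was called in 23, with log2 fold changes from -2.34 to -1.99 and a highest adjusted p of 0.0682, with Y-linked expression as a covariate. Tectb (1.44 to 1.69) was called in 11 of the 24 and Thbs4 (-1.37 to -1.10) in 12, and both kept their direction. Pknox2 was called in none. The same 3 genes were called with relative log expression or upper-quartile scaling, without a filter, with the stricter filter and with limma-voom. Totals of 16.6 to 19.4 M counts and 5 libraries per group let the simulated test find 17.9% of 1.5-fold changes, so smaller changes may be missed. The simulation held no differences between libraries that many genes share, so the real share may differ.

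For the causes of the following differences, the cause was not tested unless stated. DESeq2 called 331 genes (200 rising, 131 falling) and limma-voom with quality weights 6259 (2974 rising, 3285 falling), both with the 3 genes among them. The surrogate variable gave 10 (1 rising, 9 falling) and the removal of the length and GC trend 13 (5 rising, 8 falling), both with the 3 genes among them. The first component as a covariate, the fit without knockout 2, 3 and 5 and the test against a fold change of 1.2 each gave 1 gene (0 rising, 1 falling), Ceacam16. Fewer libraries and a stricter null hypothesis go with the last 2, and their share was not measured. A threshold of 0.1 gave 7 (2 rising, 5 falling). With Y-linked expression as a covariate edgeR called 0 (0 rising, 0 falling), with 293 genes at an unadjusted p under 0.05. Leaving out 1 library gave 1 to 166 genes (0 to 108 rising, 1 to 58 falling), with the highest number without knockout 1.

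The replicate block called 1 gene (0 rising, 1 falling), Ceacam16, and 13 lists, all 12 among them, and turned skeletal muscle to 0.057. The labels do not say that equal numbers pair the libraries. Of the 5 pairs, 2 had correlated deviations above 0.1, and 1 of the 5 knockout libraries correlated best with its own number.

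The 12 list calls became 0 (0 rising, 0 falling) with an estimated correlation and 0 (0 rising, 0 falling) with fry. Leaving out 1 library gave 9 to 16 (5 to 9 rising, 3 to 8 falling). Schwann, osteoclast and osteoblast genes were called in the same direction in all 20 other fits with the preset correlation, with medians of -0.55 to -0.17, 0.25 to 0.49 and 0.17 to 0.32.

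Lists not called in the main test were called elsewhere. Of 17 fits chosen beforehand, TALE genes passed in 8, hearing loss genes in 7 (-0.13 to -0.09, adjusted p = 0.0130 to 0.0478), immediate early genes in 7, cell cycle genes in 4, extracellular matrix genes in 3, and hair cell synapse (-0.16, adjusted p = 0.0340, without wild type 3), thyroid hormone and skeletal muscle genes in 1 each. Without knockout 2, 3 and 5 there passed immediate early genes (0.25, adjusted p = 6.48e-06), extracellular matrix (0.09, adjusted p = 0.000773), cell cycle (-0.38, adjusted p = 0.000112), skeletal muscle (-0.24, adjusted p = 0.0120) and TALE genes (0.09, adjusted p = 0.0137). With the first component as a covariate there passed the same lists but skeletal muscle, and Notch (0.11, adjusted p = 0.0470) and thyroid hormone genes (0.13, adjusted p = 0.0491), and with the length and GC trend removed extracellular matrix genes (0.16, adjusted p = 0.0102).

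Medians that moved by over 1.5 times while the call stayed were, with the surrogate variable, -0.24 for neurons, 0.13 for vestibular, 0.29 for osteoblast, -0.82 for lymphocyte and 0.09 for ribosomal protein genes, with Y-linked expression -0.28 for Schwann cell, 0.48 for osteoclast and 0.11 for heat shock genes, with the first component -0.27 for Schwann cell, 0.16 for vestibular, 0.32 for osteoblast and -0.91 for lymphocyte genes, with the trend removed 0.49 for osteoclast and 0.27 for ribosomal protein genes, and 0.29 for osteoblast genes without wild type 1.

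Directions turned as follows, where a list is counted by the direction of its test, with the median given. Potassium homeostasis, macrophages and ribosomal proteins were called in the main test, and the other results were not. No filter gave -0.014 for central nervous system and 0.048 for skeletal muscle, and fry 0.073 for middle ear. The surrogate variable gave -0.043 for hair cell identity, 0.00044 for stereocilia, -0.028 for supporting cells, -0.0031 for strial marginal cells, 0.031 for strial intermediate cells, -0.013 for central nervous system, -0.19 for middle ear, -0.036 for adipocytes, -0.024 for hypoxia and 0.080 for Wnt signalling, of which the last was called. Y-linked expression gave 0.016 for outer hair cells, 0.11 for stereocilia, -0.039 for supporting cells, 0.19 for strial marginal cells, 0.11 for strial intermediate cells, 0.025 for potassium homeostasis, 0.085 for central nervous system, -0.049 for choroid plexus, -0.0041 for cartilage, -0.074 for middle ear, -0.039 for adipocytes, -0.086 for hypoxia, 0.18 for Wnt signalling and 0.061 for hearing loss genes, with stereocilia, strial marginal and Wnt genes called, and 0.025 for Slc12a2 and -0.072 for Ttr. The first component as a covariate gave -0.057 for hair cell identity, 0.0051 for outer hair cells, 0.044 for stereocilia, -0.0089 for supporting cells, 0.032 for strial marginal cells, 0.11 for strial intermediate cells, -0.028 for central nervous system, -0.015 for choroid plexus, -0.060 for macrophages, -0.24 for middle ear, -0.080 for adipocytes, -0.078 for hypoxia, 0.12 for Wnt signalling, -0.0017 for hearing loss genes and -0.067 for ribosomal proteins, with middle ear, Wnt and ribosomal genes called, and 0.0085 for Slc12a2 and -0.044 for Ttr. In the fit without knockout 2, 3 and 5 the medians were -0.13 for hair cell identity, -0.027 for outer hair cells, 0.0032 for supporting cells, -0.0082 for strial marginal cells, 0.13 for strial intermediate cells, -0.021 for central nervous system, 0.085 for choroid plexus, -0.035 for cartilage, -0.24 for middle ear, -0.13 for adipocytes, -0.057 for hypoxia, 0.11 for Wnt signalling and -0.063 for ribosomal proteins, with middle ear and Wnt genes called. With the length and GC trend removed they were 0.054 for hair cell identity, 0.14 for tectorial membrane, 0.066 for strial intermediate cells, 0.078 for middle ear, -0.017 for adipocytes, 0.0053 for hypoxia and 0.072 for Wnt signalling. Quality weights gave -0.010 for Pknox2.

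Leaving out 1 library turned the direction in at least 1 fit for lists whose medians ran from -0.044 to 0.12 for skeletal muscle, -0.10 to 0.037 for stereocilia, -0.011 to 0.19 for middle ear, -0.11 to 0.020 for Wnt signalling, 0.0092 to 0.14 for hair cell identity, -0.23 to -0.056 for central nervous system, -0.53 to -0.18 for neutrophils, -0.36 to -0.081 for cell cycle, -0.056 to 0.044 for cartilage, -0.011 to 0.11 for extracellular matrix, -0.19 to -0.087 for supporting cells and -0.039 to 0.12 for tectorial membrane. Pknox2 ran from -0.048 to 0.15.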

Other observations

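All tests in this part were chosen after the results were seen, and the 2 gene lists were written after the table of all genes had been looked at, with 3 genes seen there among the smallest p taken off.

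Genes that rise as the cochlea matures, such as Kcnj10, Mbp and Nefh, had a median log2 fold change of -0.33 in the libraries labelled knockout, with 6 of 25 above 0 (camera p = 9.79e-05, and p = 0.0643 with an estimated correlation). Genes that fall after birth in many tissues, such as Igf2, H19, Dlk1 and Sox11, had a median of 0.14, with 19 of 25 above 0 (camera p = 0.0139, and p = 0.0798 with an estimated correlation). In the fit without knockout 2, 3 and 5 the medians were -0.18 (camera p = 0.000386, and p = 0.177 with an estimated correlation) and 0.18 (camera p = 2.77e-06, and p = 0.0248 with an estimated correlation).

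A hypothesis is that the libraries labelled knockout may come from slightly less mature tissue. Both lists passed in opposite directions in 7 of the 100 splits of the libraries, the real one included, so chance is not excluded, and delayed maturation and a chance difference between samples cannot be told apart here. The median of the rising list went from -0.33 to -0.18 without knockout 2, 3 and 5, so part of it lies in those 3 libraries. Several members of the rising list also stand on the Schwann cell, neuron and potassium lists, and litter or exact age of the pups is not given in the sources used here.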
